A study of Drosophila melanogaster with 9 samples.

How the data were processed

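Short nascent strands, the RNA-primed leading strands made just after replication starts, had been purified from 2 cultured Drosophila melanogaster cell lines and sequenced. S2-DRSC is a line of embryonic origin with haemocyte-like features, and ML-DmBG3-c2 (Bg3) is a line from the larval central nervous system. Per the labels' protocols, DNA fragments of 0.5 to 2.5 kb were collected from a gradient and treated in repeated rounds with polynucleotide kinase and lambda exonuclease, which digests DNA that lacks an RNA primer. Libraries were then made with a transposase-based kit. The pooled-fraction experiment had 2 biological replicates per line, and the single-fraction experiment on S2 cells had 2 libraries for each of fractions 4 (short fragments), 5 (middle-sized) and 6 (long), per the labels.

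The 9 samples were represented by 5 deposited origin lists, 1 for each line with replicates pooled and 1 for each S2 fraction. Per the submitters' processing notes, the tools were Bowtie2 2.2.0, SAMtools 0.1.19 and MACS 1.4.1 and the genome build was dm3. Their settings, thresholds and filters, and how replicates were combined before the regions were called, are not given in the sources used here. No list held a column per replicate, and each comparison sets 1 list against another. The Bg3 values held 2 numbers per origin, described below, but whether these are the replicates is not given in the sources used here, so no spread is called a spread between cultures. All p-values and intervals below describe positions and windows within these lists.

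Each list gave chromosome, start and end. The S2 and Bg3 lists also gave a width and an efficiency, called strength here. The deposited strength is a signal in reads per kb of the origin, as its values showed: strength times width gave whole reads (within 0.001) for 100% of S2 origins. In the Bg3 list the product was a weighted sum of 2 whole numbers, with weights 0.47268203 and 0.52731797. For 7985 of the 7998 Bg3 origins under 20000 reads exactly 1 pair of whole numbers fitted, against 2.66% of random values, and the procedure was tested on simulated data. The weights sum to 1, so a Bg3 value is a weighted mean of 2 numbers and an S2 value a whole number of reads. What the weights stand for, scaling by library size included, is not given in the sources used here. Bg3 reads are therefore not on the S2 scale, and strengths were ranked and compared within a list, and between lists only as ratios relative to the rest of the genome. Strength is the authors' own value for each origin. The reads inside listed origins came to 42.1 M for S2 and, as weighted means, 31.6 M for Bg3. The total depth of each library is not given in the sources used here, and the fraction lists carried no depth at all.

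Coordinates are printed as deposited. The smallest start was 0, whereas widths equalled end minus start plus 1, so a start may be off by 1 base. Comparisons used arms 2L, 2R, 3L, 3R and X and chromosome 4, called 6 arms here, with each arm taken to end at the last origin in any list. Origins on heterochromatic scaffolds and the mitochondrial genome were kept for the closing section. Origins were shared when they overlapped by at least 1 bp. Chance overlap came from 1000 circular shifts of 1 list within each arm (one-sided p, smallest possible value 0.000999). Intervals are 95% percentile intervals from 1000 bootstraps over 1 Mb windows, or over 500 kb windows for the ratios by arm. Intervals for the relative strength of matched origins on a stretch or arm are an exception. They drew single origins, with the value for the rest of the genome held fixed. Clustering was the share of origins with a neighbour within 5 kb, against 1000 random placements within arms. Widths were compared over whole lists and over regions that overlapped exactly 1 region in each other fraction. Local differences between the lines were tested by a two-sided exact binomial test of origin counts in 100 kb windows with at least 5 origins, with Benjamini-Hochberg adjustment at 0.05. This test treats origins as independent, although they were clustered.

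Named origins followed a rule set before the data were examined, as were these tests and most alternatives: the 5 strongest shared and 5 strongest specific origins of each line, the 3 widest regions of each fraction, up to 5 passing 100 kb windows per direction, and the densest 100 kb window of each list. No 100 kb window passed with all origins counted, and the larger windows named here were chosen after their values were seen. Alternatives covered the overlap rule (50% of both regions, 50% of the region asked about, a 500 bp gap), merging within 1 kb, the stronger origins alone, all sequences, the chance model, the neighbour distance (2 and 10 kb), window size (50 and 500 kb), the minimum count (10, or none) and leaving out each arm. In simulated lists, drawn independently of each other, a 2-fold difference was planted in some windows. The window test found 0.736% of planted 100 kb windows and 43.3% of planted 500 kb windows. With a 4-fold difference it found 53.7% and 97.7%. Overlap rules, intervals and clustering were also tested on simulated data. Annotated features, gene lists and base composition were not analysed here, because no annotation or sequence of build dm3 was used. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, SymPy 1.14.0 and Matplotlib 3.10.9.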

Results

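Replication origins had been mapped by sequencing of short nascent strands in Drosophila S2 and Bg3 cells from pooled gradient fractions, and in S2 cells also from 3 single size fractions. The S2 list held 7268 origins, of which 6456 lay on the 6 arms analysed, and the Bg3 list held 8212, of which 6728 lay on them. Fractions 4, 5 and 6 gave 4505, 6448 and 5814 regions, with 3572, 5376 and 4823 on the arms. S2 origins covered 4.78% of the arms and Bg3 origins 4.03%. Median width was 601 bp in S2 (95% interval 578 to 619) and 433 bp in Bg3 (410 to 466). The median origin held 946.5 reads in S2 and a weighted mean of 943 reads in Bg3, which are on different scales. Reads were concentrated: the top 1% of origins held 54.4% of the reads inside listed origins in S2 and 42.9% in Bg3. Each list was a single pooled set, so no difference between lists below was set against a spread between replicates.

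The first comparison asked how far an embryonic and a neural cell line use the same start sites. About 2 in 5 origins of each line were found in the other. Bg3 origins overlapped 2681 of 6456 S2 origins (41.5%, interval 39.1 to 44.1), where circular shifts gave 8.74%. S2 origins overlapped 2833 of 6728 Bg3 origins (42.1%, 39.8 to 44.3), where shifts gave 8.62%. Both shares were above all 1000 shifts (one-sided permutation p = 0.000999, the smallest possible). Among 2331 origins matched singly in both lines, the centres lay a median of 96.5 bp apart. Within S2, single fractions 4, 5 and 6 held 34.99%, 49.0% and 41.7% of the S2 pooled origins, against the 41.5% in Bg3. The fraction lists are shorter than the Bg3 list, so these shares are not like for like. In the other direction, more regions of each fraction were in the S2 list than in the Bg3 list, as given below. An origin called specific is therefore one absent from the other list, which alone does not show a difference between the lines.

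Sharing differed among the arms. On chromosome 4, the small, largely heterochromatic autosome, 32 of 43 S2 origins (74.4%) were found in Bg3, but only 31 of 106 Bg3 origins (29.2%) were found in S2. On 3L the shares were 47.4% of S2 origins and 37.4% of Bg3 origins. On 2L they ran the other way, at 38.3% and 46.5%. The X had low shares in both directions, 30.8% and 31.1%. The shared numbers were near equal in the 2 directions, at 639 and 659 on 3L and 577 and 617 on 2L. The contrasts between directions therefore mostly restate the numbers of origins. Leaving out the X raised the share of S2 origins in Bg3 given by circular shifts from 8.74% to 9.13%, so chance overlap was lower on the X. These differences between arms were not tested.

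**Figure D1:**
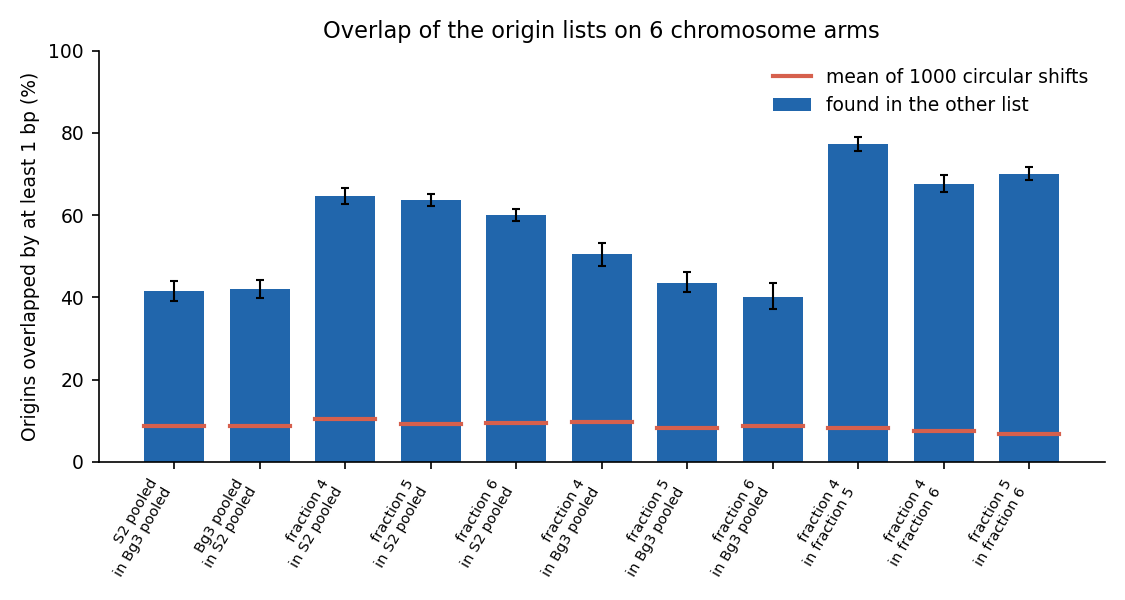
Bars give the percentage of the origins of the first list overlapped by at least 1 bp of the second, with 95% intervals from bootstraps over 1 Mb windows, and red lines give the mean of 1000 circular shifts. S2 and Bg3 share 41.5% and 42.1%, the S2 fractions lie at 59.98% to 64.6% in the S2 pooled list, and chance lies between 6.74% and 10.5%.

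Origins found in both lines were stronger than those found in 1 line. In S2 the median strength was 1715 reads per kb for shared and 1485 for specific origins, a ratio of 1.15 (interval 1.13 to 1.18). In Bg3 the medians were 2338 and 2192, a ratio of 1.07 (1.051 to 1.084). The S2 ratio was 1.08 times the Bg3 ratio (1.06 to 1.11). Of 5 equal groups by strength, the weakest S2 group had 29.9% shared and the strongest 66.8%. The same shares in Bg3 were 29.3% and 54.1%. Shared origins had medians of 737 against 530 bp in S2 and 527 against 386 bp in Bg3, but wider regions overlap more often by chance, and these ratios (1.39 and 1.37) lay within the range of the circular shifts (up to 1.42 and 1.59). By circular shifts the weakest and strongest groups would share 6.83% and 12.8% in S2 and 8.19% and 11.1% in Bg3. Across the 2331 matched origins, which are not independent replicates, strengths in the lines had a Spearman correlation of 0.373 (0.328 to 0.416). With means in place of medians the S2 ratio rose to 1.98 (1.70 to 2.26), and the Bg3 ratio was 1.203 with an interval, 0.997 to 1.39, that reached 1. From each of the 2 numbers behind the Bg3 values alone, a setting chosen after seeing the data, the Bg3 ratio was 1.09 (1.06 to 1.11) and 1.04 (1.03 to 1.06).

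**Figure D2:**
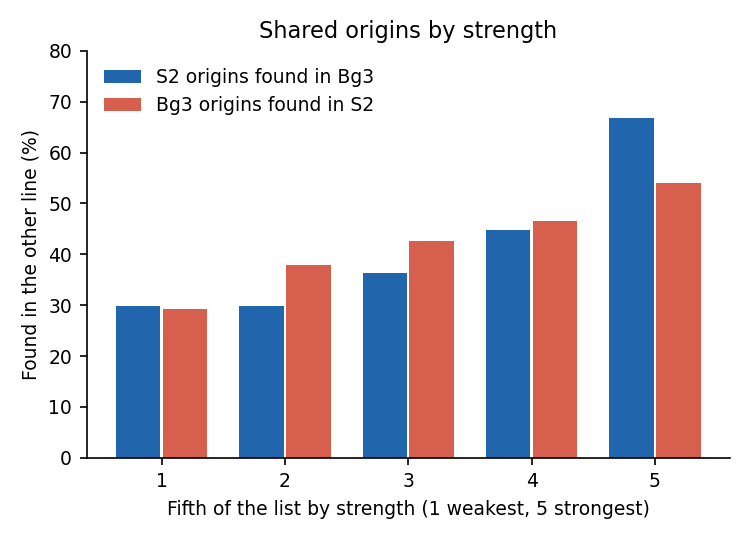
Bars give the percentage of origins found in the other line (vertical axis) for 5 equal groups of each list by strength (horizontal axis), S2 in blue and Bg3 in red. The share rises from 29.9% to 66.8% in S2 and from 29.3% to 54.1% in Bg3.

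The strongest shared S2 origin lay on 2R at 2234333 to 2239598, with 336380 reads per kb, 217 times the list median. It was followed by origins on X at 21834739 to 21835118 (263182 reads per kb), 3L at 23840938 to 23842879 (249283), 3L at 24432162 to 24436609 (219735) and 3R at 4723889 to 4730619 (185295). All 5 were found in all 3 single fractions. Among the 5 strongest shared Bg3 origins, those on X at 21833804 to 21835415 (170095 reads per kb) and on 3L at 23841651 to 23842896 (157164) overlapped S2 origins just named. The pair on X did not meet the rule of 50% overlap of both regions. The other 3 were on X at 12331631 to 12332041 (223389), X at 10196362 to 10196796 (103574) and 3L at 22781074 to 22781433 (86478).

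The strongest S2-specific origin, on 2L at 3251450 to 3259147, reached 37940.5 reads per kb and lay 41228 bp from the nearest Bg3 origin. The next 4 had nearly the same width and strength, 5379 to 5391 bp and 13576 to 14256 reads per kb. They lay on 3R at 6169019, X at 11529219, 2R at 3151461 and 3L at 404455, from 953 bp (3L) to 7336 bp (2R) from the nearest Bg3 origin. Further S2 origins were alike in width and strength, and some were found in Bg3, such as 2L at 10876497 (5380 bp, 13377 reads per kb). The strongest Bg3-specific origin was a 184 bp region on X at 8375277 to 8375460, with 885811 reads per kb, 394 times the list median. It was in none of the S2 fractions, and the nearest S2 origin was 63955 bp away. The others were on 2L at 22985917 to 22986137 (152035 reads per kb) and on X at 12387707 to 12387864 (120909), 9996408 to 9997378 (54293) and 13939849 to 13940561 (53654). Their nearest S2 origins were 629, 5417, 1188 and 10407 bp away, in that order. Thus 4 of the 5 strongest Bg3-specific origins were on the X, which held 637 of the 6728 Bg3 origins. This was not particular to specific origins, since the strong shared Bg3 origins at 12331631, 21833804 and 10196362 were on the X too. The specific ones at 8375277, 22985917 and 12387707 were only 184, 221 and 158 bp wide, against a list median of 433 bp.

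Wide origins carried much of the S2 signal. The 200 S2 origins of 4 kb or more held 62.3% of the reads on the arms. Their largest group was taken as the origin with most others within 50 bp of width and 10% of strength, together with those others. It held 24 origins of 5283 to 5357 bp and 19727 to 22874 reads per kb, ranges that this rule keeps narrow. The limit of 4 kb was chosen after the values were seen.

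**Figure D3:**
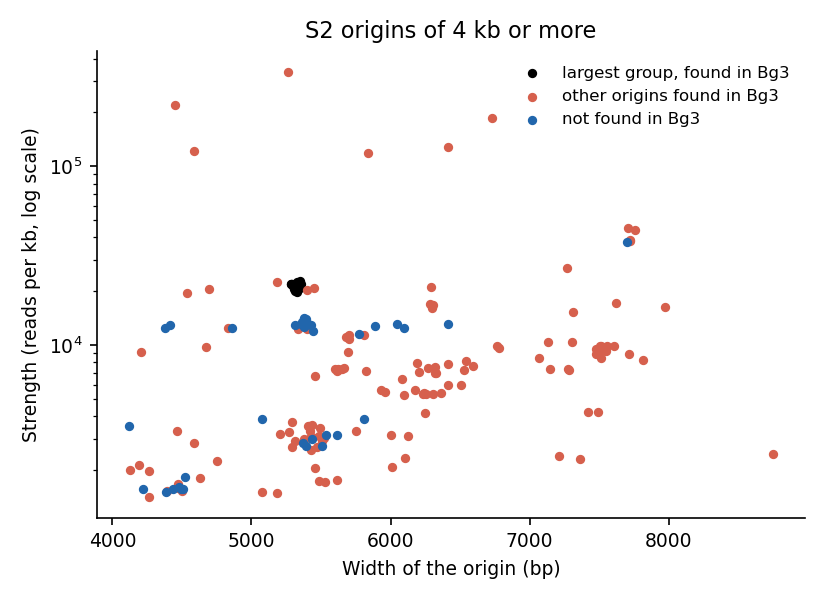
Each point is an S2 origin of 4 kb or more, by width in bp (horizontal axis) and strength in reads per kb on a log scale (vertical axis), coloured by whether Bg3 holds it. Black points are the largest group, 24 origins picked within 50 bp of width and 10% of strength of a central origin. They have 5283 to 5357 bp and 19727 to 22874 reads per kb, and all were found in Bg3.

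The X chromosome carried under 1 called origin for every 2 on the large autosomal arms. DNA copy number and read yield of the X were not examined here, so fewer origins and weaker detection cannot be told apart. In S2 there were 28.0 origins per Mb on X and 59.9 on autosomes, a ratio of 0.467 (interval 0.382 to 0.583). In Bg3 there were 28.4 and 62.0, a ratio of 0.459 (0.283 to 0.664). The Bg3 ratio was 0.982 times the S2 ratio (0.615 to 1.43), so no difference between the lines was detectable on the whole X. That value averages opposed parts: over 10 equal parts of the X, origins were denser in Bg3 in parts 1, 2 and 10 and in S2 in parts 3 to 9.

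Other arms differed between the lines in their number of origins. Relative to the remaining arms, Bg3 had more origins than S2 on 3L, 1761 against 1349 (relative ratio 1.34, interval 1.17 to 1.54). It had fewer on 2L, 1328 against 1506 (0.808, 0.714 to 0.929), and on 3R, 1432 against 1616 (0.810, 0.729 to 0.903). Chromosome 4 had 106 origins in Bg3 and 43 in S2 (2.39, 1.98 to 2.94), but its interval rests on only 3 windows. Intervals for 2R (0.967 to 1.22) and X (0.689 to 1.31) included 1.

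With all origins counted, differences were not detectable in single 100 kb windows. Of 1006 tested windows 0 passed the binomial test, 84 had an unadjusted p under 0.05, and the lowest adjusted p was 0.191. Simulated 3-fold differences were found in 19.5% of windows, but the simulated lists were drawn independently, whereas the real lists share origins. At 500 kb, 21 of 243 windows passed, 16 with relatively more origins in Bg3 and 5 with more in S2. The largest stretches with more Bg3 origins were 5 adjoining windows on X from 1.5 to 4 Mb, with 249 origins against 67 in S2 (lowest adjusted p = 2.92e-05, exact binomial test), and 6 on 3L from 0 to 3 Mb, with 454 against 222 (0.00322). The first 500 kb of chromosome 4 held 43 against 14 (0.00593). Single windows with more Bg3 origins lay on 2L from 14 to 14.5 Mb, 2R from 0 to 0.5 Mb, and 3L from 20 to 20.5 and 23 to 23.5 Mb. More S2 origins were found on X from 13 to 14 Mb, 77 against 21 (3.56e-05), and on 2L from 8.5 to 9 Mb, 46 against 13 (0.000333), with further windows on 2L from 1 to 1.5 and 15.5 to 16 Mb. With unshared origins alone, a setting chosen after seeing the data, 61 windows of 500 kb passed, and the split was even: 31 with more in Bg3 and 30 with more in S2. In that setting 18 of 793 tested 100 kb windows passed too, 14 with more in Bg3 and 4 with more in S2 (lowest adjusted p = 0.0395, exact binomial test).

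**Figure D4:**
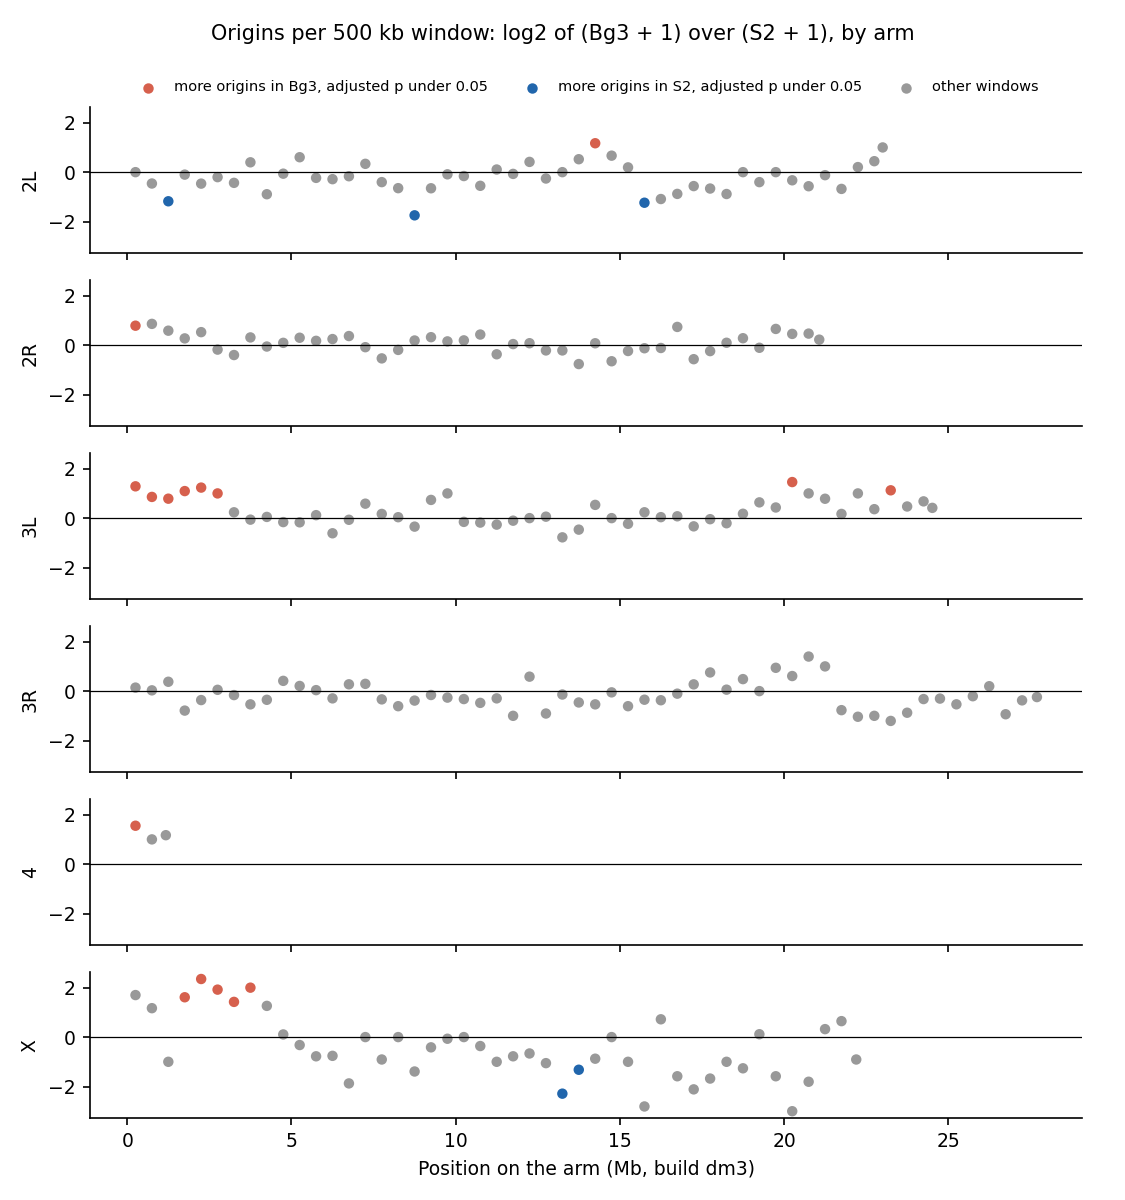
Each point is a 500 kb window, placed by its position on the arm in Mb (horizontal axis) and by the log2 of Bg3 origins plus 1 over S2 origins plus 1 (vertical axis), with passing windows in red (more in Bg3) or blue (more in S2). Red windows adjoin on 3L from 0 to 3 Mb and on X from 1.5 to 4 Mb, and blue windows on X from 13 to 14 Mb.

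Origins lay closer together than random placement gave. A neighbour within 5 kb was found for 51.2% of S2 origins (random 48.2%) and 59.2% of Bg3 origins (random 49.0%). In fractions 4, 5 and 6 the shares were 45.7%, 54.9% and 52.996%, against 31.8%, 41.9% and 38.6%. All 5 were above all random placements (one-sided permutation p = 0.000999, the smallest possible). When placements were random within 1 Mb windows in place of arms, the random value for S2 rose to 49.8% (one-sided permutation p = 0.030), so its excess was small. The densest 100 kb window held 22 origins in S2 (3L from 10700001) and 26 in Bg3 (3L from 23400001). In fractions 4, 5 and 6 the densest windows held 18 (2L from 22400001), 24 (3L from 24400001) and 21 (2R from 2300001). Merging origins within 1 kb took all 5 shares below their random values, with 36.5% against 45.0% in S2 and 44.2% against 44.6% in Bg3. When random placements were merged alike, a setting chosen after seeing the data, Bg3 (37.6% random, permutation p = 0.000999, the smallest possible), fraction 4 and fraction 5 stayed above random and S2 (36.1%, p = 0.295) and fraction 6 (28.5% against 28.1%, p = 0.305) did not.

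The single-fraction experiment asked whether short, middle-sized and long nascent strands mark the same places. Most regions of each fraction were in the S2 pooled list: 64.6% for fraction 4 (interval 62.7 to 66.7), 63.6% for fraction 5 (62.2 to 65.2) and 59.98% for fraction 6 (58.6 to 61.6). Circular shifts gave 10.5%, 9.23% and 9.52%. Fewer were in the Bg3 list, 50.5%, 43.6% and 40.1%. The difference was 14.1 percentage points for fraction 4 (11.04 to 17.003), 20.01 for fraction 5 (17.2 to 22.6) and 19.8 for fraction 6 (16.8 to 22.8). The overlaps with S2 were above all shifts (one-sided permutation p = 0.000999, the smallest possible).

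The S2 pooled origins differed in how many fractions held them. Of the 6456, 2830 were in no fraction, 862 in 1, 1034 in 2 and 1730 in all 3. Median strength was 1423 reads per kb (interval 1415 to 1434) for those in none and 2043 (1989 to 2132) for those in all 3. The share also found in Bg3 was 27.0% (24.5 to 29.7) for origins in no fraction and 62.3% (58.6 to 66.2) for origins in all 3, with 44.3% and 44.2% for those in 1 and 2. Median width rose alongside, from 482 bp in no fraction to 880 bp in all 3, and with it the share given by circular shifts, from 7.30% to 11.7%. Over these chance values the shares were 3.70-fold for origins in no fraction and 5.62-fold, 5.24-fold and 5.35-fold for those in 1, 2 and 3.

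**Figure D5:**
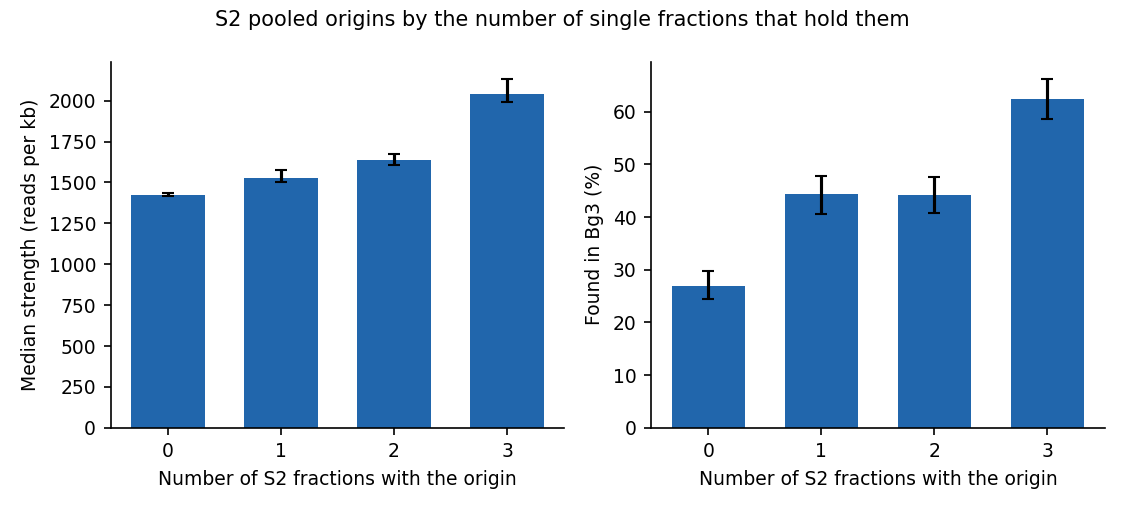
Bars give the median strength in reads per kb (left) and the percentage found in Bg3 (right) of S2 pooled origins by the number of single fractions that hold them, with 95% intervals from bootstraps over 1 Mb windows. Both are lowest for the 2830 origins in no fraction, at 1423 and 27.0%, and highest for the 1730 origins in all 3, at 2043 and 62.3%.

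The fractions overlapped each other more than the pooled lists did. Fraction 5 held 77.4% of fraction 4 regions (75.7 to 78.9) and fraction 6 held 67.6% (65.6 to 69.9), while fraction 6 held 70.1% of fraction 5 regions (68.6 to 71.7). In the other direction, fraction 4, the shortest list, held 55.004% of fraction 5 regions (52.5 to 57.5) and 52.5% of fraction 6 regions (49.9 to 55.03), and fraction 5 held 76.5% of fraction 6 regions (75.01 to 77.9). In all, 2275 of 3572 fraction 4 regions (63.7%) were in both other fractions, where shifts gave 0.81%. These shares were above all shifts (one-sided permutation p = 0.000999, the smallest possible). Centres of regions matched singly lay a median of 38.8 bp apart between fractions 4 and 5, 49 bp between 4 and 6 and 35 bp between 5 and 6. The widest regions included the same stretch of 3R in every fraction, at 26899872 to 26907636 in fraction 4, 26899901 to 26907599 in fraction 5 and 26899898 to 26907598 in fraction 6. A stretch of 3L was among the 3 widest in fraction 4 (20469815 to 20477570) and fraction 5 (20469856 to 20477538). The others were on 3L at 1505910 to 1513718 (fraction 4), 2R at 6835493 to 6843178 (fraction 5), 2L at 3059755 to 3067867 and 2R at 750858 to 758846 (both fraction 6). All but the 2L region were in the S2 pooled list, and all were in the Bg3 list.

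Regions from short fragments were not narrower. Median width was 626.5 bp in fraction 4 (interval 599 to 667), 517 bp in fraction 5 (495 to 535) and 556 bp in fraction 6 (536 to 577), so the median of fraction 4 was 1.21 times that of fraction 5 (1.17 to 1.27). After merging within 1 kb in every list this ratio was 1.09 (1.04 to 1.15). Over 1857 regions found once in each fraction the median ratio within a region was 1.01 (1.01 to 1.02) for fraction 4 over 5, 1.02 (1.01 to 1.03) for 4 over 6 and 1.00 for 6 over 5. Fraction 4 was the wider in 57.2% of them against fraction 5. The median widths of the same regions ran the other way, at 651, 711 and 705 bp in fractions 4, 5 and 6. With means of the log ratio the matched ratios fell to 0.985 and 0.979, and after merging within 1 kb to 1.00 and 1.005, with intervals that included 1.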

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

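The comparison of fractions with each other as a check on counting noise, with thinning to equal numbers, was chosen only after the 100 kb windows had given no calls, and so were the windows of 200 kb and 1 Mb and the use of unshared origins. The test on the strength of shared origins was written before its result was seen.

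In all, 4 chromosomes stood out because the number of Bg3 origins relative to S2 differed from the rest of the genome by an interval that excluded 1: 2L (0.808), 3L (1.34), 3R (0.810) and chromosome 4 (2.39). Stretches with more Bg3 origins lay on 3L from 0 to 3 Mb and on X from 1.5 to 4 Mb, although the X as a whole did not stand out. Counting noise or clustering of calls stays open in part: unshared origins of fractions 5 and 6 gave 0 passing windows at 500 kb and 0 at 1 Mb, where S2 and Bg3 thinned to the same numbers gave 11 (4 to 18 in 95% of 1000 draws) and 15 (10 to 22), but fraction 4 against 6 gave 2 and 7, where thinned lists gave 15 (6 to 23) and 19 (13 to 26), and fraction 4 against 5 gave 1 and 2, where they gave 6 (0 to 14) and 15 (9 to 22). A difference in DNA copy number or read yield of whole blocks stays open, since the strength of origins found in both lines moved with their number over 112 windows of 1 Mb (Spearman rho 0.311, interval 0.0915 to 0.500, circular-shift p = 0.000999, the smallest possible). This met the condition set beforehand, but rho was only just above its limit of 0.3, with an interval reaching far below it. From each of the 2 numbers behind the Bg3 values alone, rho was 0.347 and 0.354 over 110 windows. Shared origins on 3L from 0 to 3 Mb were 1.37-fold stronger in Bg3 relative to the rest of the genome (1.30 to 1.45). This interval and the next drew single neighbouring origins, which are not independent, so both may be too narrow. On X from 1.5 to 4 Mb the value was 1.16 (0.968 to 1.24) over 35 origins, so copy number or yield is neither shown nor excluded for the X block. A difference between the cell lines in where origins are used was not tested and stays open, as does a difference between cultures.

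On chromosome 4 the strength of the 24 singly matched origins in Bg3 relative to S2 had a log2 value of -0.48 against the other arms (-0.77 to -0.24), opposite to the excess in number, and the 2 numbers behind the Bg3 values, whose nature is not given, alone gave -0.40 (-0.70 to -0.14) and -0.29 (-0.67 to 0.12) over 20 of them, too few to settle whether the second interval includes 0, since its end moved across 0 with the random draw. Chromosome 4 also stood apart between these 2 numbers, with a median log2 ratio of 0.41 (0.33 to 0.44), where the other arms had 0.12 to 0.16. On 2L and 3L, unlike chromosome 4, the strength of matched origins in Bg3 relative to S2 differed in the same direction as their number. Its log2 value was -0.11 on 2L (-0.18 to -0.06) and 0.14 on 3L (0.10 to 0.18), while the interval for 3R (-0.08 to 0.02) included 0. These strength intervals, chromosome 4 included, drew single origins as if independent and may be too narrow. The ratio of shared to specific strength in S2 was 1.08 times that in Bg3 (1.06 to 1.11), an interval that excluded 1. Chance overlap also rose with strength, and more so in S2. From the weakest to the strongest group, circular shifts gave 6.83% to 12.8% in S2 and 8.19% to 11.1% in Bg3. The value was not corrected for this, so it does not establish a difference between the lines.

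Origins on the 6 heterochromatic scaffold sequences stayed outside the comparisons above and numbered 812 in S2, 1481 in Bg3, 933 in fraction 4, 1071 in fraction 5 and 990 in fraction 6. Their density was 1.64 times that on the arms in S2 and 2.87 times in Bg3, and they held 31.2% and 41.4% of the reads inside listed origins. Bg3 overlapped 75% of the S2 origins there (33.2% by circular shifts), and S2 overlapped 44.3% of the Bg3 origins (20.5% by shifts).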

How the results depend on the processing

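The windows of 200 kb and 1 Mb, unshared origins, joint merging, reads per origin, each Bg3 number alone, and the settings without origins of 4 kb or more or without X from 1.5 to 4 Mb were chosen only after the results were seen. Of 298 alternative values for the main results, 269 kept their direction and side of the threshold, or their size. All overlap results stayed above chance, from 23.0% to 46.3% for sharing between lines, 42.4% to 69.5% for fractions in the S2 list and 49.7% to 80.2% between fractions. For the rest, the cause was not tested unless stated. The stronger part of each list held 3228 (S2) and 3364 (Bg3) origins by construction. Merging within 1 kb turned clustering to 36.5% (S2), 44.2% (Bg3), 27.8%, 33.05% and 28.5% (fractions 4, 5 and 6), since merged origins cannot lie within 1 kb while random placements can. With both merged, S2 (36.5%) and fraction 6 (28.5%) did not pass. Merging moved the matched width ratios of fraction 4 to 1.00 (over 5) and 1.005 (over 6) and the whole-list ratios to 1.09 (over 5) and 0.988 (over 6). Means moved the matched ratios to 0.985 (4 over 5), 0.979 (4 over 6) and 1.006 (6 over 5) and the strength ratios to 1.203 (Bg3) and 1.98 (S2). Without origins of 4 kb or more the matched ratio of 4 over 5 was 1.018, no smaller, with an interval that just reached 1. The Bg3 over S2 ratio of X densities, not called, crossed 1 without 2R (1.005), without 3L (1.07) and with covered bases (1.052). Without X from 1.5 to 4 Mb it was 0.670, with an interval that excluded 1. This fall was set by construction, since that part was picked for its Bg3 excess while X from 13 to 14 Mb, with more in S2, was kept. It is therefore no separate evidence for a difference on the rest of the X. Over 10 equal parts of the X, S2 origins were the denser in parts 3 to 9. Passing windows rose from 0 to 5 with more in S2 and 16 with more in Bg3 (500 kb), 5 and 6 (200 kb), 12 and 14 (1 Mb) and 4 and 14 (unshared origins, 100 kb), while 50 kb windows and, at 100 kb, moved windows, merging, a minimum of 10 and no minimum gave 0. Unshared origins gave 30 and 31 at 500 kb and 22 and 21 at 1 Mb. Moved 500 kb windows gave 22. No paired analysis was possible because the lists hold no column per replicate and the 2 numbers in the Bg3 values are not identified as replicates, and leaving out named replicates was not run for the same reason. Also not run were the stricter threshold for the fraction lists, which carry no strength, annotated arm lengths, annotated features, gene lists and base composition. Depth may limit these shares, which was not tested: reads per library are unknown, so an origin missing from a list could lie just under its calling limit. The overlap rule matters too, since sharing fell to 23.0% where 50% of both regions had to overlap.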

Other observations

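The tests on wide origins, on empty windows, on merged widths and on fraction 5 regions missing from fraction 4 were chosen only after the result was seen, and the remaining tests on widths before it.

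Windows without origins coincided in the lines, mostly on the X. Of 1207 windows of 100 kb, 18 held no origin in either line, 14 of them on X, where circular shifts within arms gave a mean of 9.43 (one-sided permutation p = 0.0020). The log2 ratio of S2 over Bg3 origin numbers in a 500 kb window was correlated with that in the next window (Spearman rho 0.493 over 238 pairs of windows). For the ratio of fractions 5 and 6 rho was 0.229, and for fractions 4 and 5 it was 0.0339. The fraction ratios also varied less (SD 0.323 and 0.439, against 0.775 for S2 and Bg3), so these values are not like for like and were not tested against each other. These are correlations across windows, which are not independent replicates.

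Very wide origins held much of the signal. In S2, 200 origins of 4 kb or more were 3.10% of the list and held 62.3% of the reads on the arms, and in Bg3 175 such origins held 35.8%. Of the S2 ones 80% were found in Bg3. The largest group, picked by likeness in width and strength, was 24 S2 origins on 5 arms. They had widths from 5283 to 5357 bp and strengths from 19727 to 22874 reads per kb, ranges that the picking keeps narrow. Their median strength was 14.1 times the list median. All 24 were found in Bg3 and in all 3 fractions. The 4 S2-specific origins of 5379 to 5391 bp named above had a similar likeness to each other and to further S2 origins. Some of these further origins were not in Bg3, such as 2L at 7977013 (5401 bp, 13323 reads per kb). Others were, such as 2L at 10876497 (5380 bp, 13377 reads per kb).

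In S2, 131 of the 200 had another within 50 bp of width and 10% of strength, where permuted strengths gave a mean of 94.6. Among the 175 in Bg3 the likeness was weaker, under the highest permuted number (mean 84.2, one-sided permutation p = 0.011). Reads of dispersed repeats spread over their copies could give such groups and stay open: of 283 such pairs found singly in Bg3, 85.2% also had Bg3 strengths within 10%, against a mean of 64.1% with widths permuted (one-sided permutation p = 0.0060). Without the group of 24 the share was 66.7% of 42 pairs against 33.3% (permutation p = 0.019), short of the 0.01 set for this test. The excess over the permuted mean was no smaller than with the group, but far fewer pairs were left. Joining of neighbouring peaks stays open, since 30.96% of the 197 S2 ones that overlap fraction 5 cover several of its regions, between the bounds set for it. No sequence of these places was used here, so neither repeats nor active origins within them can be named.

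Fraction 4 regions were 1.21 times as wide as fraction 5 regions over whole lists. Joining of neighbouring peaks in fraction 4 is argued against as the whole cause, since 7.996% of overlapping fraction 4 regions held several fraction 5 regions, but it stays open for a part, since merging within 1 kb lowered the ratio to 1.09 (1.04 to 1.15). The composition of the lists may account for most of the difference, which fell to 1.01 (1.01 to 1.02) in matched regions: fraction 5 regions found in fraction 4 were 1.66 times as wide as those not found in it (1.59 to 1.73), 671 against 405 bp. Wider regions also overlap more often by chance, and the 1.66 was not set against circular shifts. The small remainder in matched regions argues against composition as the whole cause, although the remainder was not seen after merging or with means, and the median widths of the same regions, 651 bp in fraction 4 and 711 bp in fraction 5, ran the other way. Fragment size, which the fractions differ in by design, stays open for the remainder and was not tested.

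What the 2 numbers behind each Bg3 value are, replicates or other sets of reads, is not given in the sources used here. Over 6558 origins on the arms their log2 ratio had an SD of 0.28, and 3.58% of origins lay over 1.5-fold from the median ratio. Their Spearman correlation was 0.963 across origins, which are not independent replicates. The median absolute deviation of the log2 ratio was 0.16 for Bg3 origins shared with S2 and 0.17 for specific ones.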
